A study of Mus musculus with 15 samples.

How the data were processed

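Gene expression was measured on Affymetrix Mouse Gene 2.1 ST arrays in 15 samples of type II alveolar epithelial (AT2) cells, the surfactant-producing cells of the lung's air sacs. Per the labels' protocols, the cells were enriched by depleting cells with the endothelial marker CD31 and the leukocyte marker CD45 and were then sorted by flow cytometry, and the total RNA was not treated with DNase before the column step. Each array received labelled cDNA made from 225 ng of RNA. The submitters' processing notes name Affymetrix Expression Console, RMA (robust multi-array average, which subtracts background, normalizes between arrays and summarises probes) and Partek. Their versions and the genome build are not given in the sources used here, so no coordinates are printed. The values deposited by the authors are on the log2 scale, as the range of the measured values shows, and they were used without a further transformation.

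The same values were deposited in 2 tables, a workbook and a value table, which differed by at most 5e-09 on the log2 scale. Each table has 31351 rows, and a check of the values showed that only the first 324 (1.03%) vary from row to row like measurements. In each of the 15 columns the remaining 31027 rows lie on the least-squares straight line through that column's first 324 rows, continued by row number, to within 2.5e-13. These later values climb to 41.8, beyond the measured range, and carry no information about the genes named beside them. What produced the lines is not recorded in the sources used here. All straight-line rows were left out of every step, because a test can turn the slopes of the lines into calls. The limma model described below called 30837 of those 31027 rows as lower with Tregs present than in control, when it was run over the table as deposited. It called 30263 as higher with Tregs depleted than with Tregs present, and 0 with Tregs depleted against control.

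The measured rows are in alphabetical order of transcript name, and 312 of the 324 carry a name that starts with AK. By symbol, 260 rows were predicted genes or cDNA clones and 64 had another name. The file's gene numbers matched 108 rows to a RefSeq gene table for the mouse assembly GRCm38.p6, of which 60 were protein coding. Symbols were kept as the file gives them, and the pairing of names with values was taken as deposited. It could not be checked, since no well-known marker gene of AT2 cells is among the measured rows, and this doubt bears on every gene named. For 34 of the measured rows the same symbol also stands beside a straight-line row, so such a row is only a part of what the array holds for that gene. No column of values per sample was left unused. For arrays, the number of samples limits the precision, and most measured rows lie near the floor: the median over rows of the mean value was 2.32, and 46 rows had a mean over 4.

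Samples were grouped by the title and description in the labels into control, resolving with Tregs (regulatory T cells) present and resolving with Tregs depleted, with 5 arrays each. The analysis was set before the data were examined. A single row with the highest mean stood for each symbol, and genes were kept when they exceeded the array's median in at least 5 of the 15 arrays. The median was taken over the measured rows, and 173 of 323 symbols were kept. A linear model with 1 mean per group was fitted to all 15 arrays with limma 3.58.1 (lmFit, contrasts.fit and eBayes with a mean-variance trend) in R 4.3.3. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and intervals are 95% confidence intervals from the same model. All adjusted p-values in the text come from limma unless another test is named. The design had assumed a full array of genes, and the model was kept as written on the measured rows. Equal replicate numbers were not taken to pair samples, since the labels tie no number to a shared mouse, litter or day.

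Named genes followed a rule: for each comparison, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, passing over predicted genes, RIKEN clones, small RNAs and receptor families, plus up to 4 members of each gene list. Fewer genes met the rule than it allows. Predicted or clone genes and Lcp2 were chosen after their values were seen. Of 30 gene lists fixed beforehand, 27 had no measured gene and 3 had 1 each, so no list could be tested as a set. The 8 genes that were to be named in any case, among them the markers Foxp3, Sftpc and Ptprc, lie on the straight lines and are not analysed here. The same holds for the marker lists of other cell types.

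The fit was tested on simulated data: 173 genes with the means and spread of the real ones, of which 10 each were changed by 0.5, 1 or 2 log2 units in the Treg-depleted group, in 40 simulations of the comparison of Tregs depleted with Tregs present. It recovered 75.2% of the changes of 0.5, 97.8% of those of 1 and 99.5% of those of 2, and 4.05% of its calls were false. These shares hold for sets with that many changed genes, drawn independently of each other, with the spread as moderated by limma. The changed genes were drawn at random from all 173, of which 127 had a mean of 4 or less, and recovery was not split by level. Genes with a wider spread would be recovered less often: the standard error of this difference was 0.193 for Lpin2 and 0.069 for Aqp4, a gene near the floor. Where fewer genes change, the adjusted threshold is stricter and fewer changes would be recovered. Alternatives covered the filter on low values, the variance model, array weights, the replicate number as a block, median centring, quantile normalization, stricter thresholds and leaving out each array in turn. Outlying samples were sought with Dixon's ratio (critical value 0.71 for 5 samples). Figures were drawn with matplotlib 3.10.9.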

Results

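The study asked how AT2 cells differ in lungs that are recovering from acute injury, and whether regulatory T cells (Tregs), which carry the transcription factor Foxp3 and restrain inflammation, alter that state. Lung injury was produced in mice by instilling bacterial lipopolysaccharide (LPS) at 3 mg/kg into the trachea, and the resolving groups were taken at day 7. Control AT2 cells came from C57BL/6 mice, resolving AT2 cells with Tregs present from Foxp3EGFP mice, in which Tregs are fluorescent, and resolving AT2 cells with Tregs depleted from Foxp3DTR mice, whose Tregs can be killed with diphtheria toxin. Each group had 5 arrays. Mouse strain therefore changed with the group in every comparison, and the treatment text can be read as giving LPS to all 3 strains although one group is called control. A second description line in the labels speaks of Tregs as the profiled cells, of the lung or, for 3 of the Treg-depleted arrays, of the spleen. The labels leave open whether the mice with Tregs present also received diphtheria toxin. The labels do not say that each array is a separate mouse, so p-values measure the spread between these samples.

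The deposited tables hold measurements for 324 of 31351 rows, and all values below come from those rows. On these, the 15 arrays had medians between 2.25 and 2.39 on the log2 scale. Correlations between arrays across the measured rows ranged from 0.951 to 0.984 within groups and from 0.929 to 0.984 between groups, and no 2 arrays were identical. The first principal component of the 173 tested genes held 42.7% of the variance. All 5 control arrays lay between -4.99 and -1.66 on it and the 10 resolving arrays between -0.16 and 3.46. The filter and test could see only these genes, mostly clones and predicted genes, so counts of changed genes describe this small part of the array and not the AT2 transcriptome.

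The comparison of resolving AT2 cells with Tregs present against control asks what injury and recovery had changed. Clu, which encodes the secreted chaperone clusterin and belongs to the list of transitional AT2 genes, rose from 7.63 ± 0.21 in control to 8.78 ± 0.12 (SD, n = 5 each). This is a log2 change of 1.15 (95% interval 0.88 to 1.41), or 2.21-fold, with an adjusted p of 2.59e-06. D17H6S56E-5, a protein-coding gene, rose most, from 5.54 ± 0.12 to 7.60 ± 0.27, which is 4.18-fold (adjusted p = 3.21e-09). Lpin2, a phosphatidate phosphatase of glycerolipid synthesis, fell by 1.28 on the log2 scale (interval -1.68 to -0.87, adjusted p = 9.77e-05), from 9.18 ± 0.14 to 7.91 ± 0.52. Ryr2, a calcium release channel of the endoplasmic reticulum, fell by 1.11 (adjusted p = 0.000113), from 4.16 ± 0.44 to 3.05 ± 0.15. The lower level is closer to the floor, so the size of this fall is less certain.

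In all, 28 of the 173 tested genes changed, 5 up and 23 down, and 12 of them by at least 2-fold. The groups did not overlap for 18 of the 28, and for 19 of all 173, where chance gives 0.794% of genes or 1.37. Prr16 and Klf11 also met the naming rule. Prr16 rose by 0.66 (adjusted p = 0.000152) and the Krüppel-like transcription factor gene Klf11 fell by 0.52 (adjusted p = 0.00725), both at low levels. Prr16 stood at 2.42 ± 0.10 in control, near the array medians that mark the floor, so its change is measured against a level not shown to be above background. Lpin2 was measured by the row AK048657, a cDNA clone, and its symbol also stands beside a row not analysed here.

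Most changed genes had no established name. Predicted or clone genes made up 21 of the 28 (75.0%), close to their share of the tested genes (126 of 173, 72.8%), and 19 of them fell, while 4 of the 7 with another name fell (two-sided Fisher's exact p = 0.0825). The largest falls among them, chosen after their values were seen, were those of Gm10590 (-1.68, adjusted p = 1.13e-06), D130062J21Rik (-1.67, adjusted p = 8.49e-05) and Gm10914 (-1.53, adjusted p = 0.000532). The predicted gene Gm20559 rose by 0.89 (adjusted p = 0.00139). The balance of directions depended on the scaling: after quantile normalization 27 genes were called, 14 up and 13 down, and Klf11 was no longer among them. The 5 rises and 12 of the 23 falls were called both ways.

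Against the same control arrays, resolving AT2 cells with Tregs depleted also had higher D17H6S56E-5 and Clu and lower Lpin2 and Ryr2. D17H6S56E-5 rose to 7.81 ± 0.14 (SD, n = 5), which is 4.83-fold above control (adjusted p = 6.70e-10), and Clu to 8.75 ± 0.22, a log2 change of 1.12 (interval 0.86 to 1.39, adjusted p = 3.53e-06). Lpin2 fell by 0.97 (interval -1.37 to -0.56, adjusted p = 0.00149) to 8.22 ± 0.24, and Ryr2 fell by 0.95 (adjusted p = 0.000716) to 3.21 ± 0.12. Prr16 rose by 0.56 (adjusted p = 0.000875), Klf11 fell by 0.53 (adjusted p = 0.00822), and D5Ertd683e, an expressed DNA segment, fell by 0.66 (adjusted p = 0.0336).

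Here 19 of the 173 genes changed, 5 up and 14 down, and 8 of them by at least 2-fold. The groups did not overlap for 16 of the 19, and for 18 of all 173. Of the 12 predicted or clone genes among them (63.2%) 10 fell, and of the other 7 genes 4 fell (two-sided Fisher's exact p = 0.305). Gm20559 rose by 1.17 (adjusted p = 0.000184), while Gm10914 (-1.38), Gm10590 (-1.37) and Gm19439 (-1.27) fell most, all chosen after their values were seen. After quantile normalization 19 genes were called, 7 up and 12 down, and Klf11 and D5Ertd683e lost their calls. Leaving out control 1, 2 or 5 or Treg-depleted 1 or 5 also ended the call of D5Ertd683e.

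**Figure D1:**
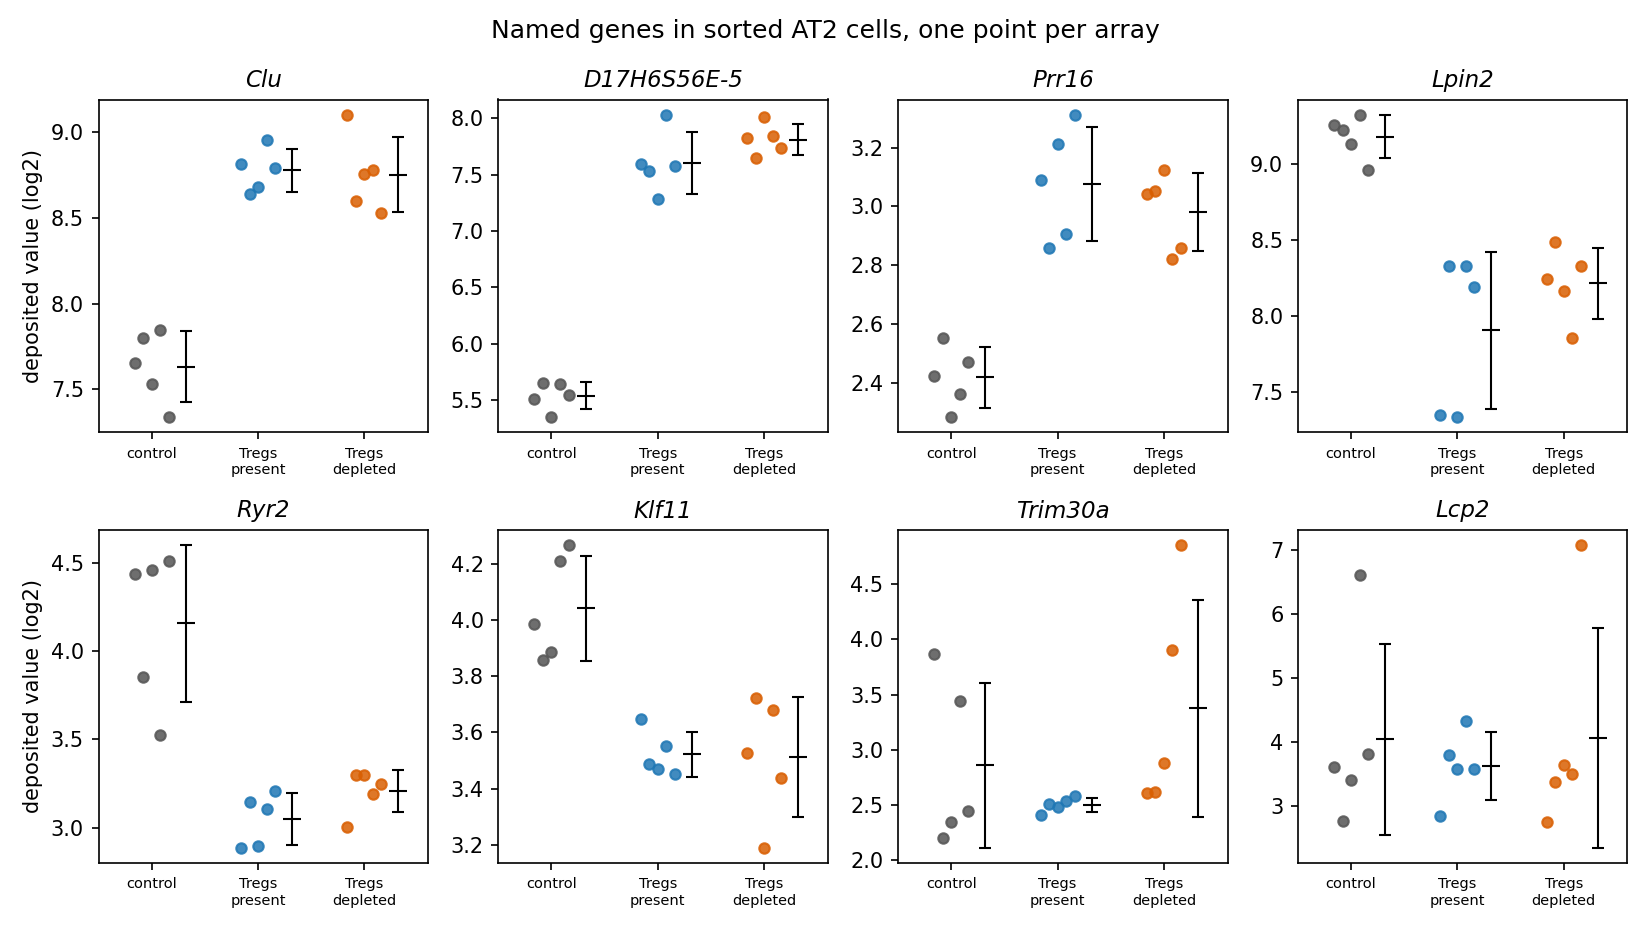
Deposited log2 values of 8 genes in sorted AT2 cells, with 1 point per array, 5 arrays per group, and the group mean with its SD beside the points (vertical axes do not start at 0). Clu, D17H6S56E-5 and Prr16 lie higher, and Lpin2, Ryr2 and Klf11 lower, in all 10 resolving arrays than in any control array (after quantile normalization Klf11 was not called). Lcp2 stands at 6.61 in 1 control array and 7.07 in 1 Treg-depleted array.

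Both comparisons with control called 17 genes in the same direction, 4 up and 13 down, and none in opposite directions. The rises were those of D17H6S56E-5, Clu, Gm20559 and Prr16. Independent lists of these lengths would share 0.145 genes up and 1.86 down. The log2 changes of the 173 genes had r = 0.892 across genes, which are not independent replicates. In 100 simulations of unchanged groups, shared controls alone gave a median r of 0.496, at most 0.81, and at most 1 shared call. The simulated genes were drawn independently of each other. Real arrays can share deviations across genes, so the simulated range may be too narrow. The covariance was 0.161 against 0.0134 in the simulations, a difference of 0.148. With the 5 controls split between the comparisons in all 20 ways, 5 to 14 genes were called in both (median 10) and r was 0.649 to 0.797.

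**Figure D2:**
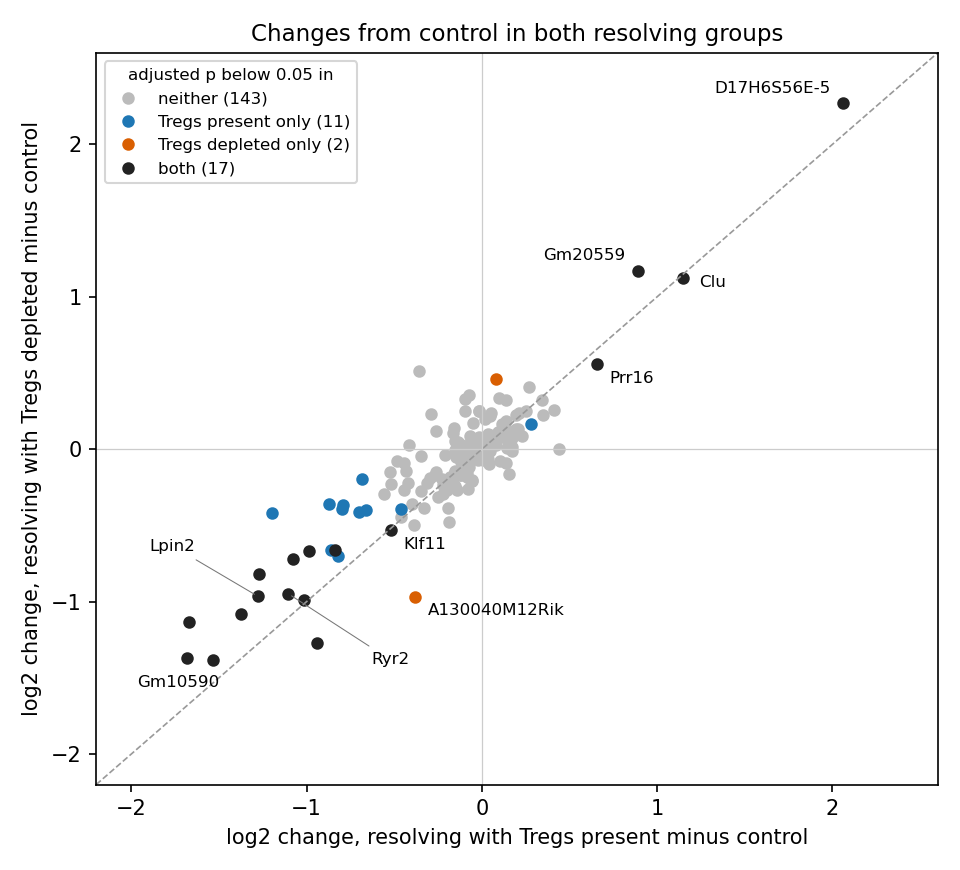
Log2 change from control of the 173 tested genes with Tregs present (horizontal axis) and with Tregs depleted (vertical axis), 1 point per gene, coloured by the comparisons in which the adjusted p was below 0.05. The dashed line marks equal changes. The 17 genes called in both lie in the upper right and lower left, 11 were called with Tregs present only and 2 with Tregs depleted only, a split that is not a test of the difference between the groups.

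The comparison of resolving AT2 cells with Tregs depleted against Tregs present addresses the study's main question. For named genes that had moved from control, the measured differences were smaller than those changes. Changes in the same direction from shared controls favour this by arithmetic, so it says nothing about an effect of Treg depletion. Clu differed by -0.02 on the log2 scale (95% interval -0.29 to 0.24), D17H6S56E-5 by 0.21 (-0.08 to 0.49), Klf11 by -0.01 (-0.28 to 0.26) and Lpin2 by 0.31 (-0.10 to 0.72). After quantile normalization these differences were -0.37 for Clu, -0.10 for D17H6S56E-5, whose sign turned, -0.17 for Klf11 and 0.05 for Lpin2, and none was called. None of the 173 genes was called by limma, and none by an ordinary linear model without moderation. At an unadjusted p under 0.05 there were 14 genes, where 8.65 would be expected by chance. The median half-width of the 95% interval was 0.28 log2 units, and larger differences also stay undecided where a gene's spread was wide or its adjusted p missed the threshold.

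The largest difference over all arrays was that of Trim30a, an interferon-induced gene and the measured member of the type I interferon list. It stood at 3.37 ± 0.98 with Tregs depleted and 2.50 ± 0.06 with Tregs present (SD, n = 5), a log2 difference of 0.87 (interval 0.07 to 1.67, adjusted p = 0.527). Its unadjusted p from limma was 0.0354. An adjustment over the list alone leaves this value unchanged, since only 1 gene of the list of 28 was measured. The 2 groups did not overlap for Trim30a, Gm20115 and D130012P04Rik, 3 of 173 genes where chance gives 1.37, and control arrays spanned 2.21 to 3.87 for Trim30a. Its level with Tregs present lay near the floor and is not shown to be above background, so the size of the difference is uncertain. Without Treg-depleted 5, the difference in Trim30a was 0.50, below that of 0.78 in Gm19816 over all arrays, and its change from control went from 0.51 to 0.14. The clone A130040M12Rik, chosen after its values were seen, was lower with Tregs depleted by 0.59 (interval -0.92 to -0.26, adjusted p = 0.252). It passed the test (adjusted p = 0.0384) when only the 46 genes with a mean over 4 were tested, a restriction chosen after seeing the data, and its adjusted p lay between 0.0513 and 0.531 in the 19 alternatives in which values of single genes were recomputed.

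Each of the 3 fixed lists with a measured gene had 1. With 1 measured gene, an adjustment over the list alone leaves the p-value unadjusted. Lpin2, of the list for fatty acid and phospholipid synthesis, and Clu, of the transitional AT2 list, passed in both comparisons with control, unadjusted and adjusted over all genes. Neither passed between the resolving groups (adjusted p = 0.697 and 0.999). Trim30a did not pass against control with Tregs present (log2 change -0.36, adjusted p = 0.618) or depleted (0.51, adjusted p = 0.425). One leukocyte gene, Lcp2, which encodes an adaptor of T cell and myeloid receptor signalling, varied widely between arrays. It stood at 6.61 in control 4 and 7.07 in Treg-depleted 5 and between 2.75 and 4.33 in the other 13 arrays, and Trim30a was also highest in Treg-depleted 5, at 4.85. Without these 2 arrays, an alternative added after seeing the data, the 3 counts of called genes were 32, 21 and 0.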

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

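The tests of leftover leukocytes, of wrong labels, of a shift of whole arrays, of leftover genomic DNA or unspliced RNA, and of the shape of the value distribution were chosen only after the values had been seen. Among 78 sets of 5 arrays (named genes and array-level measures), 5 had an array far from the other 4, where about 1 in 20 or 3.9 would be expected by chance. The count is not a test of an excess of far values. Lcp2 was named after its values were seen, and other genes were named because their groups did not overlap. Gm10590 was 6.10 in control 4 against 6.69 to 6.91 in the other controls, and Gm5859 was 5.66 in control 4 against 6.41 to 6.69. D5Ertd683e was 3.49 in Treg-depleted 1 against 3.84 to 3.97 in the others of its group. The remaining 2 far values were those of Lcp2, 6.61 in control 4 against 2.78 to 3.81 and 7.07 in Treg-depleted 5 against 2.75 to 3.64.

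For the height of Lcp2 in these 2 arrays no biological explanation was tested. A fault that moved many genes by over 1 log2 unit is argued against, since Lcp2 was the only 1 of 173 tested genes that lay so far outside the other 13 arrays in both. A smaller fault stays open, as 127 of the 173 genes had a mean of 4 or less. Both arrays lay above the other 13 in 2 genes, Lcp2 among them, and below in 4, where chance gives 1.90% of genes either way. The 2 arrays' deviations from their group means correlated across genes at 0.598. Without Lcp2 the value was 0.339, rank 3 of 75 pairs from different groups, where another pair reached 0.353. On the second principal component (15.6% of the variance) they stood apart at 3.57 and 4.45, against at most 0.72 in the other 13, but without Lcp2 they lay at 1.23 and 2.86, against at most 1.77. An exchange between control and resolving is also argued against: on the mean of 17 genes called both ways without these 2 arrays, the highest control, which was control 4, stayed 0.531 below the lowest resolving array, against a group SD of at most 0.209. An exchange between the resolving groups stays open, since on that mean Treg-depleted 5, at -1.961, lay within the range of both (-2.001 to -1.688 with Tregs present, -2.157 to -1.802 in the other Treg-depleted arrays). Leukocytes left after the CD45 depletion may be a source and cannot be told apart from other sources here, because 0 of the 3 other leukocyte genes (Nckap1l, Rcsd1 and Slamf6) had both arrays above the other 13, but their means of 2.23 to 2.38 lie at the floor and abundant leukocyte transcripts such as Ptprc are not analysed here.

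Most genes called against control were predicted or clone genes that fell (such genes were 72.8% of those tested), and this was weighed against 3 technical explanations. A shift of all measured rows by one amount is argued against, since the median change with Tregs present was -0.0184 over all 323 genes (SD of the changes 0.345) and -0.94 over the 23 falls. Centring the arrays moved the median by at most 0.0065 and decides nothing. Most of the 323 genes lie near the floor and set that median. A shift confined to the 46 genes with a mean over 4, of which 22 were called with Tregs present, was not tested. Genomic DNA or unspliced RNA left in the control samples stays open: control minus resolving had a median of -0.0097 over the 161 genes whose mean lay below the median gene's, but normalization between arrays would remove a general lift of such genes. A difference in the shape of the value distribution cannot be told apart from a true excess of falls, because a share of 0.522 of the 23 falls kept their call after quantile normalization, which on so few rows also removes a real one-sided change. Recovery from injury and mouse strain were not separated and stay open.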

How the results depend on the processing

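The analyses without control 4 and Treg-depleted 5 together, those restricted to genes with a mean over 4 and the leave-outs for genes shared by both comparisons were chosen after seeing the data. Counts of called genes stayed within 1.5 times the reported ones (28 with Tregs present, 19 with Tregs depleted, 0 between them) in all alternatives but these. At least 2-fold change left 12 and 8 genes, since it is the stricter rule, and a mean over 4 gave 1 gene between the resolving groups with 46 genes tested. Splitting the controls left a median of 10 genes called in both comparisons against 17, with fewer controls in each fit. Leaving out 1 array gave 19 to 31 genes with Tregs present, 15 to 24 with Tregs depleted, 0 between them in all 15 fits, and 13 to 19 genes called in both. Whichever array was left out, 19 of the 28 and 15 of the 19 genes kept their calls. With the replicate number as a replicate block the counts were 25, 20 and 0. No pairing by equal numbers was seen: residual correlations had a median of 0.0033 in the 15 same-numbered pairs and 0.0244 in other pairs. Of the same-numbered pairs, 3 had a value over 0.1 (range -0.25 to 0.33). Of the 15 arrays, 4 correlated best with their own number, for which no chance rate was computed. Most rows lie near the floor, so these values cannot exclude a shared day or litter. The 29 called values of named genes that were recomputed kept direction in all 551 alternative fits and lost the call in 9, 4 of them under quantile normalization (Klf11 in both comparisons, Gm10099 with Tregs present, D5Ertd683e with Tregs depleted) and 5 by leaving out an array (D5Ertd683e). The calls of Gm20559 with Tregs present and of Gm20115 with Tregs depleted were not among them. Signs turned only for uncalled values: leaving out 1 array moved Lcp2 between -0.73 and 0.23 with Tregs present, between -0.72 and 0.67 with Tregs depleted and between -0.31 and 0.77 between the resolving groups, and Clu between -0.112 and 0.0313 there. For Lcp2, 0.23 and 0.67 arose without control 4, and -0.72 and -0.31 without Treg-depleted 5, the 2 arrays where it was high. For Clu the cause was not tested. Gene list tests with camera or fry and their alternatives were not run, since each list had at most 1 measured gene. Signal over background limits the low genes: 127 of the 173 tested genes had a mean of 4 or less and gave 6 of the 28 and 5 of the 19 calls.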

Other observations

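Against control, 2 genes were called with Tregs depleted and not with Tregs present, a clone and a predicted gene. A130040M12Rik was 7.69 ± 0.26 in control, 7.31 ± 0.17 with Tregs present and 6.73 ± 0.28 with Tregs depleted, with log2 changes from control of -0.38 (adjusted p = 0.115) and -0.97 (adjusted p = 0.000249). Gm20115 rose with Tregs depleted (0.46, adjusted p = 0.00823), from 3.06 ± 0.16 to 3.52 ± 0.17, against 3.14 ± 0.09 with Tregs present. Neither was called between the resolving groups after adjustment over all 173 genes (adjusted p = 0.252 for each). Gm19816 had the opposite order, with a change of -1.20 with Tregs present (adjusted p = 0.00127) and -0.42 with Tregs depleted (adjusted p = 0.301), and a difference of 0.78 (interval 0.28 to 1.28, adjusted p = 0.252).

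Chance division of the arrays was tested by drawing 100 splits of the 10 arrays of each comparison, the real one included. For Tregs present against control, 1 split, the real one, gave 28 or more genes, and the highest of the others gave 23. For Tregs depleted against control, again only 1 split, the real one, reached 19 genes, and the highest of the others gave 17. A chance division of the arrays that reaches these counts was therefore rare for both, at 1 of 100 splits. This takes the arrays as independent, which the labels do not say. Between the resolving groups 0 genes were found, so all 100 splits had to give as many and the count says nothing about chance (the highest gave 3). For genes at an unadjusted p under 0.05, 12 of 100 splits gave 14 or more, up to 24, so chance is not excluded for them.

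A hypothesis drawn from the plot of both comparisons was that changes from control may be smaller on average when Tregs are depleted. Over the 27 genes that passed for the average of both resolving groups against control, a choice that treats the groups alike, 21 had moved less with Tregs depleted. The mean change in each gene's own direction was 0.84 with Tregs depleted and 0.99 with Tregs present, a difference of -0.15 (exact two-sided permutation p = 0.206 over 252 divisions of the 10 arrays). The difference lay in the 22 falls (-0.20, exact permutation p = 0.159), while the 5 rises had a mean of 1.09 with Tregs depleted and 1.02 with Tregs present (exact permutation p = 0.302), although 3 of the 5 were smaller with Tregs depleted. Chance spread between arrays can therefore give a difference of this size, while the 2 arrays with high Lcp2 did not make it, since without them it was 1.09 times as large (-0.16).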
